A study of Bradyrhizobium diazoefficiens USDA 110 with 8 samples.

How the data were processed

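RNA of soybean root nodule bacteroids and of free-living cells of the nitrogen-fixing soil bacterium Bradyrhizobium diazoefficiens was compared on 2-colour arrays. Per the labels, bacteroids were harvested from nodules 4 weeks old, free-living cells were grown in HM medium with arabinose, and RNA was extracted with hot phenol. Per the labels' protocols, 20 µg of total RNA was copied into cDNA with random primers, and 4 µg of cDNA was labelled with Cy3 or Cy5. Each of the 8 arrays held both cell types, and the series design describes 4 independent biological replicates of each cell type. Each replicate was hybridised on a forward array, with bacteroids in Cy5, and on a dye-swapped array, with bacteroids in Cy3.

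The deposited table holds 1 log ratio per probe and array, read here as a log2 ratio, for 8480 probes, with no missing values. The log base, the scanner, the background correction and the normalization are not given in the sources used here. The array medians lay between -0.10 and 0.08, so the authors' deposited values were centred near 0. A shift of all transcripts in one direction would be removed by such centring, and a ratio here is relative to the average gene. If the values are natural logs, every fold is larger than stated and the p-values do not change. The table gives no signal per channel, so dim spots could not be told from bright ones, and the number of arrays limits the precision.

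The direction of the ratio was settled only in part. The label writes the ratio in the order of the channels, which would turn the sign between forward and swapped arrays. Yet all pairs of arrays correlated positively across probes (Pearson r from 0.73 to 0.93). The swapped arrays had thus already been turned in the deposited values. Before the data were examined, a rule was set for such a case. Signs would be given in the direction in which the genes of nitrogen fixation and of respiration at low oxygen are higher in bacteroids. Both groups are known to be expressed there and not in aerobic cultures. The low-oxygen list went both ways (8 of 16 members on one side and 4 on the other), so the direction rests on the nitrogen fixation list. Positive values are therefore likely bacteroids over free-living cells. In the mirrored reading every sign, and each "higher" and "lower", is exchanged.

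Probes were named through the array platform's annotation, which dates from its design and can be old. Of the 8480 probes, 1469 had a gene symbol, 6993 had a locus tag alone and 18 were not listed, with no probe listed under several symbols. Probes of 1 locus were averaged, which gave 8267 loci, of which 8074 had 1 probe, 173 had 2 probes and 20 had 3. No probe was marked as a plant, control or spike-in sequence, so plant RNA in the bacteroid preparation was not measured. No genome coordinates were used. The number in a locus tag follows the gene order along the chromosome and serves as its position.

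The forward and swapped array of a replicate were averaged, and the 4 means per locus were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over 8267 loci). Loci past this threshold are called higher or lower, and those with a fold of at least 2 are counted beside. Errors are SDs over the 4 replicate means. The same procedure on simulated data with 200 changed loci among 8267 recovered 47% of the changes of 0.5 on the log2 scale and 100% of those of 1 and of 2, with 13 false calls among 178. In the data 5445 loci were called, far more than were changed in the simulation, so its figures do not carry over to the comparison.

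Gene lists were fixed before the data were examined, as patterns of gene symbols, products and locus numbers. Because no products were at hand, membership rests on symbols and locus numbers, and 5 of 33 lists had under 3 members and were not tested. These were the aminoacyl-tRNA synthetases, transposases, ABC transporters and the histidine kinases with response regulators, with 0 members each, and the sugar uptake list, with 2 members (xylA and xylB). The 28 others were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the lists, and with an estimated correlation. The estimated form takes its degrees of freedom from the 4 replicates, so it has little power here. A list that does not pass it is not thereby shown to be unchanged. The symbiosis island block (locus numbers 1600 to 2100) was compared with the rest of the genome by Fisher's exact test, two-sided, and by 10000 random draws of as many loci. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

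The genes named were chosen by a rule set before the data were examined. It took the 12 highest and 12 lowest loci with a symbol among those past the threshold with 1 sign in all replicates and both orientations. It added up to 4 members per list with the smallest adjusted p, and a fixed set of well-known genes. Where a count of 5 or fewer fell outside the rule, its members are named as well, and these were chosen after their values were seen. Alternatives were other scalings, arrays as samples with a replicate block, each dye orientation alone, other variance models and fold bounds, another rule for several probes, each replicate left out, and other list tests and memberships.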

Results

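The arrays compared bacteroids, the nitrogen-fixing form that rhizobia take inside root nodules, with free-living cells of the same strain grown on arabinose. Values are mean log2 ratios of bacteroids over free-living cells, with the direction likely on the basis of the nitrogen fixation genes and the log base taken as 2, and errors are SD over n = 4 replicates. The 8 arrays, in 4 dye-swap pairs, measured 8267 loci each. Means of the replicates correlated across loci with Pearson r from 0.89 to 0.95 (genes are not independent replicates), and the median SD between replicates was 0.27. The depth of an array, as signal over background, is unknown.

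In bacteroids, most measured genes of nitrogen fixation, hydrogen uptake, nodulation and phosphate uptake were higher, and most of those of ribosomes, ATP synthase and NADH dehydrogenase were lower. Amino acid synthesis (53 of 91 lower, 14 higher) and flagellar genes (29 of 57 lower, 5 higher) were mixed. By camera at its preset correlation 7 lists were higher and 7 lower, and with an estimated correlation 0 lists were higher and 0 lower. This loss is not due to gene correlation alone. For flagellar genes the estimate, -0.0142, lay below the preset 0.01, yet the unadjusted camera p rose from 0.00298 to 0.0341. For chaperones (estimate -0.0033) it rose from 0.00992 to 0.0574. The other called lists had estimates above 0.01. With 4 replicates the estimated form has little power. In all, 5445 of 8267 loci (65.9%) passed an adjusted p of 0.05 in limma, with 2706 higher and 2739 lower in bacteroids. At least 2-fold changes were fewer among the higher loci (655) than among the lower ones (1128), but the farthest changes lay on the higher side. A log2 ratio of at least 4 was found at 74 loci, and one of -4 or less at 12. All 4 replicates had the same sign at 5908 of all loci (71.5%), where chance gives 12.5%. Such repetition shows how steady a probe's ratio is, not that the probe measures its gene. At 83 loci with a plain and a suffixed probe name, both probes passed when tested separately, and at 27 of these with opposite signs. Read as natural logs, the values give 1276 loci at least 2-fold higher and 1736 lower. When a fold of 2 itself was the bound of the test, 929 loci passed, 373 higher and 556 lower. With ordinary t statistics 3719 loci passed, 1641 higher and 2078 lower, so the even split depends on the variance model.

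Nitrogen fixation genes had the farthest rise of the tested lists. Of 23 measured members 19 were higher, each at least 2-fold, with a list median of 4.58 on the log2 scale. The genes of nitrogenase itself were at 6.06 ± 0.72 for nifH, which encodes the reductase component, 5.81 ± 0.39 for nifD and 5.56 ± 0.38 for nifK. For nifD the forward arrays gave 6.86 and the swapped ones 4.76 (adjusted p of the difference 0.0508). The transcriptional activator nifA was at 4.29 ± 0.27, and fixR (blr2036), which lies just before it, at 6.03 ± 0.36. Outside these were nifS (blr4342) at -0.78 ± 0.26 and a further fixR copy (bll2623) at -0.73 ± 0.29, both lower. A nifS copy (blr4338) at 0.19 ± 0.26 and nifR (blr4486) at -0.25 ± 0.42 did not pass. These loci lie outside the island block and are members by symbol alone, so a role in nitrogen fixation is not shown for them. The list's camera adjusted p was 4.12e-12, and its adjusted p = 0.337 with an estimated correlation. Without its members in the island block (genes of more than 1 list), the list had a median of -0.49 and did not pass (adjusted p 0.367). Its direction is not independent evidence, since the sign of all values was taken from it.

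**Figure D1:**
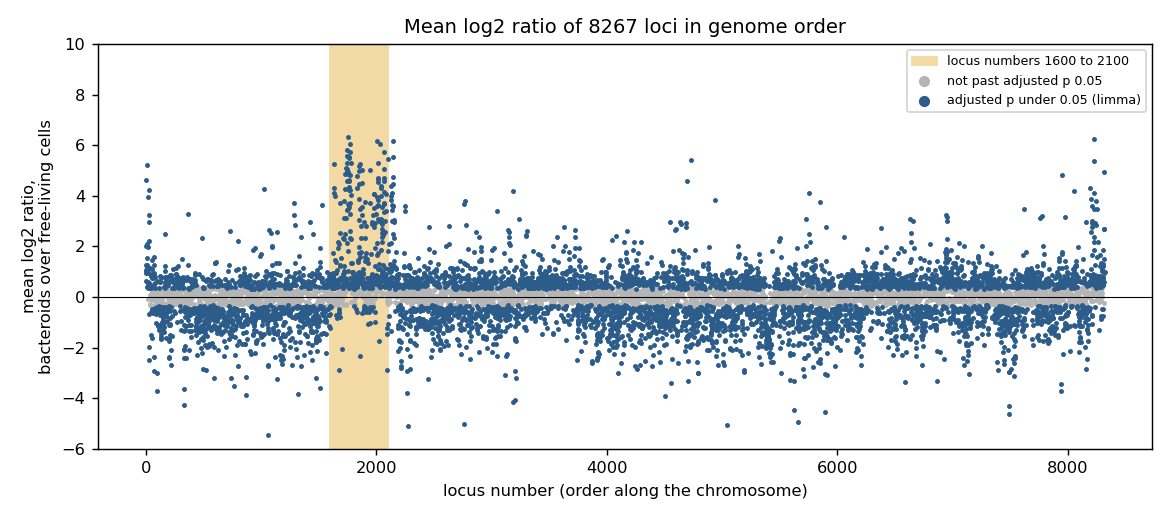
Mean log2 ratio of bacteroids over free-living cells (y axis) of each of 8267 loci against locus number (x axis), with loci past an adjusted p of 0.05 in blue and the others in grey. The shaded block of locus numbers 1600 to 2100 holds 52 of the 74 loci with a log2 ratio of at least 4.

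The block of locus numbers 1600 to 2100 was taken for the symbiosis island, the stretch of the chromosome that carries the nodulation and nitrogen fixation genes. It was higher as a whole, and the island's own limits were not used. Of the block's 481 measured loci, 329 were higher and 37 lower, or 68.4% and 7.69%, against 30.5% and 34.7% of the 7786 loci outside. The odds of a higher call were 4.92 times those outside (95% confidence interval 4.03 to 6.05, Fisher's exact test, p = 4.72e-61), which treats neighbouring genes as independent. In a Monte Carlo permutation test with 10000 random draws of as many loci, none had such a share (p = 0.0001, the smallest they can give). Of 8267 contiguous blocks of the same size, 127 held as many higher loci, and none of these lay clear of the island block, where the highest count was 234. The highest count of any block was 342, in a block that started at locus number 1683. The block held 117 of the 257 loci with a log2 ratio of at least 2. Named members beside the nif genes were bsr1758 at 6.34 ± 0.41, nfeC (bll2067), known for nodulation efficiency, at 5.73 ± 0.28 and nrgC (bll2063) at 5.05 ± 0.15. The camera adjusted p of the block was 3.85e-18, and the adjusted p = 0.301 with an estimated correlation.

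Nodulation factor genes were higher by less. Of 31 members 25 were higher and 3 lower, with a median of 0.61. Examples were nolA, a regulator, at 4.55 ± 0.27, nolZ at 3.07 ± 0.18 and nodD2, a LysR-type regulator, at 3.00 ± 0.28, while nodC, the chitin oligosaccharide synthase of Nod factor synthesis, was at 0.78 ± 0.16. The 3 lower ones were nodQ at -1.76 ± 0.30, nodA at -1.73 ± 1.02 and nodN (blr3959) at -1.50 ± 0.22. Of these, nodQ (bll1475), near cysD and cysH, and nodN lie outside the island block. So do nodI (blr0906) and another nodN (bll3460), which were higher. All of these outside loci are members by symbol alone, which does not show a role in Nod factor synthesis. The list's camera adjusted p was 0.000252, and its adjusted p = 0.337 with an estimated correlation. Without its members in the island block, which belong to more than 1 list, it did not pass and its median was -0.33 (adjusted p 0.65). The call of nodA, with replicates from -2.84 to -0.40, is lost with ordinary t statistics (adjusted p 0.0763).

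Genes of the uptake hydrogenase, which oxidises the hydrogen released by nitrogenase, were higher at 25 of 35 members, 14 of them at least 2-fold, and lower at 3. The large subunit hupL was at 3.26 ± 0.42 (bll6941) and at 1.23 ± 0.22 in the copy within the island block (blr1721), and hupH (blr1727) was at 4.28 ± 0.24. Lower were hypB (bll6931) at -0.39 ± 0.40, hupV (bll6943), a sensor hydrogenase subunit, at -0.42 ± 0.26, and hupA (bll6175) at -2.08 ± 0.63, a symbol also used for the histone-like HU protein, which is no hydrogenase. The camera adjusted p was 7.63e-06, and the adjusted p = 0.337 with an estimated correlation. Denitrification genes were higher at 11 of 19 members and lower at 2 (camera adjusted p 0.0214, adjusted p = 0.337 with an estimated correlation). Among them the nitrate reductase genes napB and napA were at 1.57 ± 0.38 and 0.95 ± 0.21, and the nitrous oxide reductase gene nosZ at 1.51 ± 0.06. The nitrite reductase gene nirK, at 0.24 ± 0.32, did not pass (adjusted p 0.174), except in replicates 3 and 4 alone (0.51, adjusted p 0.0109). The regulator nnrR was lower at -1.30 ± 0.29, as was norE (blr3212) at -0.58 ± 0.28.

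Genes of respiration at low oxygen and their regulators went both ways, with 8 of 16 higher and 4 lower, and the list did not pass (median 0.36, camera adjusted p 0.269). Within the fixNOQP set, which encodes the high-affinity cbb3-type terminal oxidase, fixP was at 3.79 ± 0.17 and fixQ at 3.68 ± 0.33, while fixN was at -0.13 ± 0.15 and did not pass (adjusted p 0.393). The gene between fixN and fixQ, fixO (blr2764), was at 1.36 ± 0.86, with 2.67 on forward arrays and 0.05 on swapped arrays. The regulator genes went both ways. Higher were the fixK copies bll2109 at 1.11 ± 0.39 and bll3466 at 0.78 ± 0.24. Lower were fixJ at -0.62 ± 0.27, not past the threshold on swapped arrays alone (adjusted p 0.0592), fixL (bll2760) at -0.44 ± 0.42, fixK (bll7696) at -1.10 ± 0.32 and fixK (bll2757), next to the sensor pair fixLJ, at -5.01 ± 0.67. A further fixK copy (bll6061), at -0.28 ± 0.32, did not pass, nor did fixG (blr2767) at 0.03 ± 0.20 and fixS (bsr2770) at 0.02 ± 0.72. For bll2757 the forward arrays gave -3.69 and the swapped ones -6.33.

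**Figure D2:**
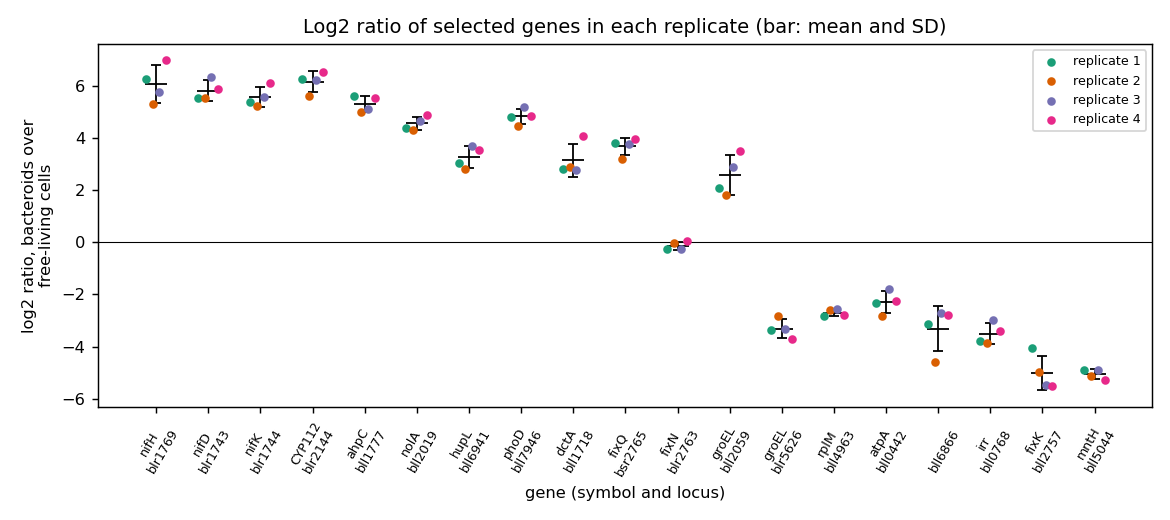
Log2 ratio of bacteroids over free-living cells (y axis) of 19 named genes (x axis) in each of 4 replicates (coloured points), with the mean and SD as black bars. The replicates of nifH lay at 5.29 or higher, and those of fixK (bll2757) at -4.07 or lower.

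Phosphate uptake genes were higher at 9 of 11 members, 7 of them at least 2-fold (median 1.69, camera adjusted p 0.000252, adjusted p = 0.388 with an estimated correlation). The gene phoD (bll7946) was at 4.82 ± 0.30, the phosphate-binding protein gene pstS at 2.53 ± 0.51 and phoU at 2.00 ± 0.30, while phoH (bll0794) was lower at -0.92 ± 0.45. The trehalose and compatible solute list had 4 members, all higher, but its call (camera adjusted p 0.045, adjusted p = 0.388 with an estimated correlation) was lost without replicate 2 (adjusted p 0.0523) and without replicate 3 (adjusted p 0.0617). It was lost too on forward arrays alone (median 0.31, adjusted p 0.0885), with the probe of median size (0.158) and in replicates 1 and 2 alone (0.069). Its ectoine synthase gene ectC was at 5.47 ± 0.58, and the others lay between 0.35 (betB) and 0.63 (otsA). The calls of otsB, at 0.36 ± 0.25, and of betB, at 0.35 ± 0.12 as the mean of probes at -0.33 and 1.03, were lost when single replicates were left out, otsB without replicate 2 or 3 and betB without replicate 2, 3 or 4. On forward arrays alone neither passed (adjusted p 0.219 for otsB and 0.168 for betB), nor did they in replicates 1 and 2 alone (0.11 and 0.225). betB also failed on swapped arrays alone (0.0605) and with the probe of median size (-0.33, adjusted p 0.0688), and otsB with ordinary t statistics (0.104) and in replicates 3 and 4 alone (0.063). Of 4 oxidative stress genes, ahpC and ahpD of alkyl hydroperoxide reductase were higher at 5.30 ± 0.30 and 2.32 ± 0.27, and the list did not pass (camera adjusted p 0.269). A further member, sodF, was lower at -0.63 ± 0.51, with -0.11 on forward and -1.15 on swapped arrays. It lost its call on forward arrays alone (adjusted p 0.579), with ordinary t statistics (0.135), in replicates 3 and 4 alone (0.323) and without replicate 1 (0.0549).

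Ribosomal protein genes were lower in bacteroids without exception: 52 of 52 passed, 42 of them at least 2-fold, with a median of -1.55. Examples were rpsD at -3.13 ± 0.20 and rplM at -2.70 ± 0.13, and rpsA was at -1.22 ± 0.42. The camera adjusted p was 1.92e-16, and the adjusted p = 0.337 with an estimated correlation. Of 12 genes of RNA polymerase and translation factors 9 were lower and none higher (camera adjusted p 0.00601, adjusted p = 0.388 with an estimated correlation). The elongation factor genes fusA and tuf were at -2.21 ± 0.33 and -1.53 ± 0.13, and rpoC was at -1.40 ± 0.43. The 3 that did not pass were rpoB at -0.22 ± 0.30, prfA (blr0218) at -0.02 ± 0.47 and infA (bsl1446) at 0.30 ± 0.33.

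Genes of ATP synthase and of NADH dehydrogenase, the entry of the respiratory chain, were lower too. All 8 ATP synthase genes were lower (median -1.38, camera adjusted p 0.000252, adjusted p = 0.337 with an estimated correlation), with atpA at -2.31 ± 0.42 and atpD at -1.15 ± 0.40. Of 13 genes of NADH dehydrogenase (complex I) 11 were lower, with nuoA at -1.97 ± 0.44 (median -1.25, camera adjusted p 0.000176, adjusted p = 0.337 with an estimated correlation). The others, nuoE (bll3138) at -0.34 ± 0.32 and nuoC (bll4917) at -0.27 ± 0.29, did not pass. Of 19 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase 11 were lower and 4 higher, with a median of -0.57, and the list missed the threshold (camera adjusted p 0.0698) but passed without replicate 1 (adjusted p 0.0449) and in replicates 3 and 4 alone (0.0281). It passed too on swapped arrays alone, where its median was -1.09 (adjusted p 0.011), and with genes of more than 1 list left out (median -0.80, adjusted p 0.0385). Lower genes included sdhD at -1.90 ± 0.33, mdh at -1.76 ± 0.43 and the citrate synthase gene gltA at -1.21 ± 0.19. The 4 higher ones were citA (bll1864) at 1.79 ± 1.60, fumC at 0.64 ± 0.31 (bll0286) and 0.66 ± 0.40 (blr6519), and lpd (blr3722) at 0.60 ± 0.29. The call of citA, a member by symbol alone whose SD is close to its mean, rests on limma's moderated variance.

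**Figure D3:**
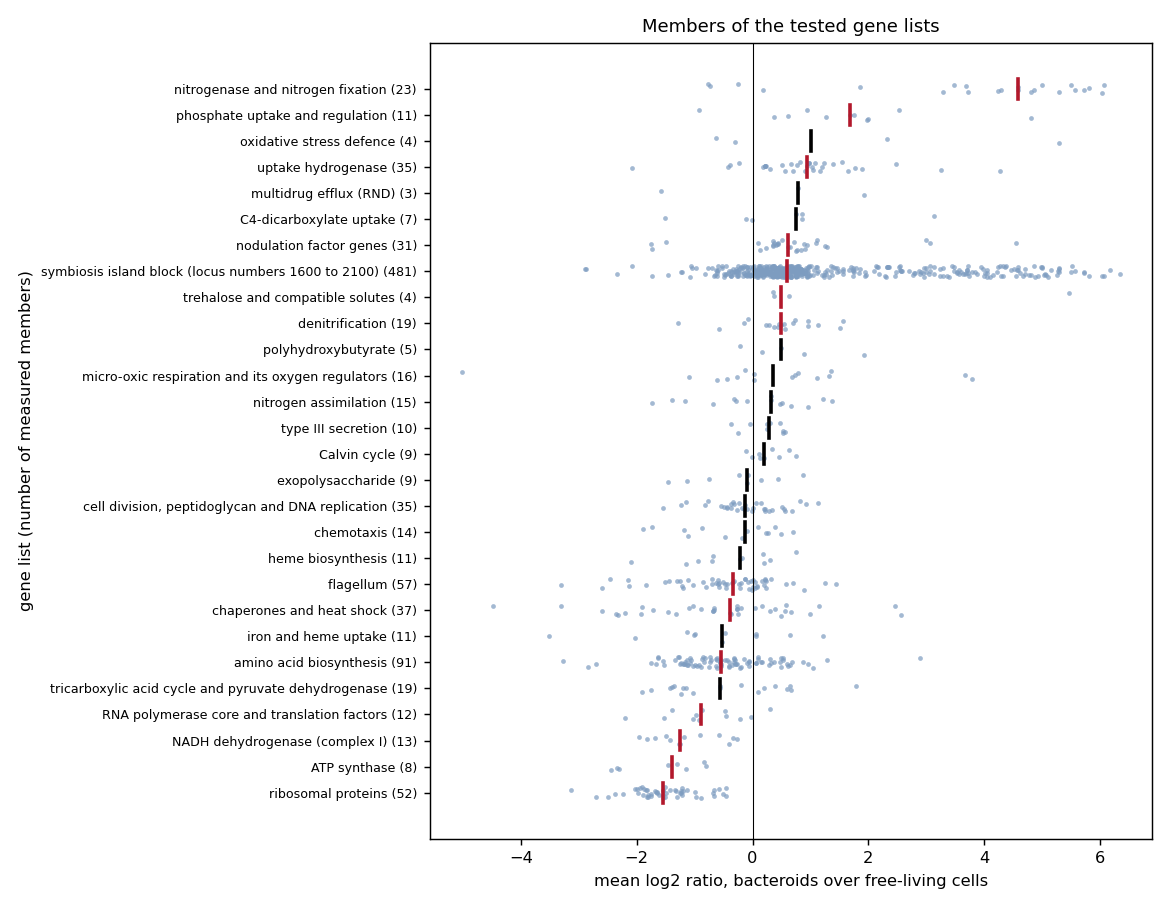
Mean log2 ratio of bacteroids over free-living cells (x axis) of each measured member of 28 gene lists (y axis, with the number of members), in order of list median. Vertical bars are list medians, red where the camera adjusted p was under 0.05 at the preset correlation, and run from -1.55 for ribosomal proteins to 4.58 for nitrogen fixation.

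Amino acid biosynthesis genes were lower at 53 of 91 members and higher at 14 (median -0.54, camera adjusted p 0.000298, adjusted p = 0.43 with an estimated correlation). The serine acetyltransferase gene cysE was at -3.28 ± 0.13, leuD at -2.84 ± 0.40 and the aspartate kinase gene lysC at -2.70 ± 0.28, against trpD (bll2049), which lies in the island block, at 2.90 ± 0.25. The list's patterns also take in cysS and metG, which encode tRNA synthetases. Nitrogen assimilation genes showed no common direction, with 7 of 15 higher and 4 lower, a median of 0.32 beside a mean of 0.01, and a camera adjusted p of 0.789. The glutamine synthetase gene glnA was at -1.73 ± 0.06, and both glnK copies passed in opposite directions, at 1.37 ± 0.14 (blr0612) and -1.17 ± 0.49 (blr0606). The other lower ones were ntrX at -1.40 ± 0.40 and glnB (blr4948) at -0.69 ± 0.26.

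Flagellar genes were lower at 29 of 57 members and higher at 5 (median -0.34, camera adjusted p 0.00759, adjusted p = 0.337 with an estimated correlation). Flagellin genes were among the lower ones: bll6866 was at -3.32 ± 0.86, fla (bll6865) at -2.15 ± 0.40, and the neighbours bll5843 to bll5846 lay between -2.59 and -1.22. The gene annotated fliC (bll6855) was at -0.81 ± 0.24. The 5 higher ones were motC (bll6861) at 1.44 ± 0.39, fliR (bll5810) at 1.25 ± 0.33, flhA (bll6851) at 0.88 ± 0.51, flgG (bll6873) at 0.70 ± 0.09 and flgI (bll6871) at 0.57 ± 0.16. Chemotaxis genes, with 6 of 14 lower and 3 higher, did not pass as a list (camera adjusted p 0.29), with cheY (blr2342) at -1.89 ± 0.48 (-2.58 forward and -1.20 swapped). The 3 higher ones were mcpK (bll0383) at 0.70 ± 0.58, cheR (blr2196) at 0.50 ± 0.19 and cheW (bll0392) at 0.38 ± 0.19.

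Chaperone genes split by copy. Of 37 members 20 were lower and 8 higher (median -0.39, camera adjusted p 0.0214, adjusted p = 0.337 with an estimated correlation), and the list did not pass when loci with a difference between dye orientations were left out, though its median stayed at -0.33 (adjusted p 0.0562). The groEL copy in the island block (bll2059) was at 2.57 ± 0.76. The other copies were at -3.31 ± 0.36 (blr5626), -1.93 ± 0.51 (blr7533) and -1.03 ± 0.33 (blr6979), and at -0.28 ± 0.24 (blr5227), which did not pass (adjusted p 0.0996). The co-chaperone gene groES (blr5625), beside blr5626, was at -4.48 ± 0.59, and dnaK was at -2.35 ± 0.32. Forward and swapped arrays differed for groES, at -3.18 and -5.79, and for groEL (blr5626), at -2.52 and -4.11. Near-identical copies can share signal on an array, so these values are uncertain to that extent. The sigma factor genes rpoN1 and rpoN2 were at 1.11 ± 0.51 and, not past the threshold, -0.29 ± 0.35. rpoN2 passed without replicate 4 (-0.44, adjusted p 0.0339) and in replicates 1 and 2 alone (-0.57, adjusted p 0.0106).

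**Figure D4:**
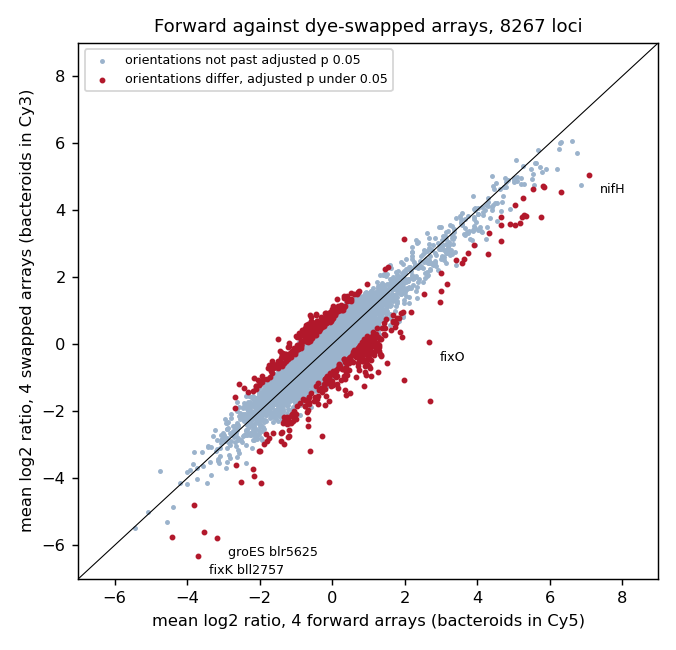
Mean log2 ratio on the 4 swapped arrays (y axis) against that on the 4 forward arrays (x axis), both as bacteroids over free-living cells, for 8267 loci. The line marks equal values, and red points are the 560 loci whose orientations differed at an adjusted p under 0.05 (limma).

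The remaining lists did not pass camera over all loci. C4-dicarboxylate uptake (adjusted p 0.29) rested on 7 dctA copies, of which bll1718, in the island block, was at 3.13 ± 0.62, blr3723, bll7095 and blr3840 were between 0.76 and 0.86, and blr4298 was lower at -1.52 ± 0.14. The calls of blr3723, bll7095 and blr3840 were lost with ordinary t statistics (adjusted p 0.0706, 0.0908 and 0.0979), and that of blr3840 also on swapped arrays alone (0.0541) and in replicates 3 and 4 alone (0.056). Iron and heme uptake (adjusted p 0.123) had 7 of 11 lower, with the iron response regulator irr at -3.51 ± 0.41, bacterioferritin bfr at -2.03 ± 0.35 and fur at -0.998 ± 0.34, and 2 higher, hmuR at 1.21 ± 0.48 and exbD (bll7072) at 0.64 ± 0.31, and it passed among genes with 1 probe only (median -0.76, adjusted p 0.0431). Heme biosynthesis (adjusted p 0.269) had 5 of 11 lower, with hemA at -2.11 ± 0.41 and hemE, hemH (bll0812 and bll7752) and hemF between -1.15 and -0.68, and hemN1 (bll2007) higher at 0.76 ± 0.32. Polyhydroxybutyrate (adjusted p 0.156) had phbB at 1.92 ± 0.19, phbC at 0.89 ± 0.27 and phbA at 0.48 ± 0.19 higher among 5 members, and phbA lost its call on forward arrays alone (adjusted p 0.0572) and in replicates 3 and 4 alone (0.0695). Type III secretion (adjusted p 0.289) had rhcV, rhcT, rhcC2 and rhcN higher, between 0.48 and 0.56, and rhcC1 (bll1811) lower at -0.37 ± 0.29, and rhcN lost its call without replicate 1 (adjusted p 0.0749) or without replicate 2 (adjusted p 0.115). It was lost too on swapped arrays alone (0.224), with ordinary t statistics (0.147) and in replicates 3 and 4 alone (0.431). rhcV lost its call on forward arrays alone (0.28, adjusted p 0.125), and rhcC2 on swapped arrays alone (0.22, adjusted p 0.376) and with ordinary t statistics (0.0503). The Calvin cycle (adjusted p 0.269) had cbbS and cbbY higher at 0.74 ± 0.45 and 0.63 ± 0.22 among 9 members, and cbbS lost its call with ordinary t statistics (adjusted p 0.0802) and in replicates 3 and 4 alone (0.052). Cell division, peptidoglycan and DNA replication (adjusted p 0.587) had 7 of 35 higher and 12 lower. Exopolysaccharide (adjusted p 0.471) had exoM at 0.88 ± 0.34 and ndvB (blr4614) at 0.44 ± 0.39 (0.88 on forward arrays, -0.0012 on swapped ones) higher, and pssA, exoN and exoT lower between -1.46 and -0.75. Multidrug efflux (adjusted p 0.471) had acrA at 1.93 ± 0.24 and acrB at 0.79 ± 0.15 higher and tolC lower at -1.59 ± 0.22. Adjusted over the list alone, the counts of higher and lower members equalled those over all loci in every list except the island block (332 higher), NADH dehydrogenase (12 lower), chaperones (9 higher) and oxidative stress defence (2 lower).

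Outside the lists, cytochrome P450 genes CYP112 at 6.15 ± 0.40 and CYP114 at 5.52 ± 0.38 were among the highest. Among the lowest were the manganese transporter gene mntH at -5.04 ± 0.19, the lactoylglutathione lyase gene lguL at -4.63 ± 0.42, the pilin gene pilA at -3.34 ± 0.52, the carbonic anhydrase gene cah at -3.23 ± 0.34, ctpA (bsl7141) at -3.05 ± 0.21 (-1.97 forward and -4.13 swapped) and cyc1 at -2.96 ± 0.39.

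The spread had a dye component. Arrays of a dye-swap pair correlated with r from 0.80 to 0.89, forward arrays with each other from 0.90 to 0.93 and swapped arrays from 0.79 to 0.88. The orientations differed at 560 loci (6.77%, limma adjusted p under 0.05), and at 66 called loci their means had opposite signs. nifH was among the 560, at 7.08 on forward and 5.05 on swapped arrays. Replicates 1 and 2 (r 0.93), and 3 and 4 (r 0.95), resembled each other more than any across these pairs (r up to 0.92), and 69 loci differed between the pairs. Within replicates 1 and 2 alone 5314 loci were called, and within 3 and 4 alone 4459, of which 4874 and 4223 were called with the same sign over all 4. Each pair is part of the fit over all 4, so this overlap is partly built in and is no independent replication.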

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

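The fixK and fixN tests were chosen after the results were seen, while those on the block of locus numbers 1 to 31 were set down before its values per orientation and replicate were seen, but after the block had been picked for its high median over all arrays. In 7 of 166 genes named, 1 replicate lay far from the other 3 by Dixon's test, which chance passes for about 1 in 20 groups, and no list median did so. Replicate 2 was far for fixO (blr2764), at 2.65 against 0.91 to 0.95, for tuf, at -1.72 against -1.49 to -1.45, for dnaK, at -2.82 against -2.22 to -2.15, and for cheW (blr2346), at -1.40 against -1.13 to -1.10. Replicate 4 was far for ectC, at 6.34 against 5.14 to 5.22, and for dctA (bll1718), at 4.06 against 2.77 to 2.90. Replicate 1 was far for the flagellin gene bll5846, at -2.40 against -2.67 to -2.64. Over all loci 388 (4.69%) passed, with replicate 2 the far one at 140.

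fixK (bll2757), a regulator that the fixLJ pair is known to activate at low oxygen, was far lower in bacteroids while fixQ and fixP were higher. A dye effect of this gene as the whole cause is argued against by the orientation nearer to 0, at -3.69 ± 0.99 over 4 arrays. Signal from another fixK copy is argued against as well, since the lowest of these, bll7696, was at -1.10. A probe that hybridises with another transcript, and a true fall of the regulator's RNA in mature bacteroids, stay open as hypotheses.

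The 30 measured loci numbered 1 to 31, at the start of the locus numbering and far from the island block, had a median of 1.12, with 28 higher and bll0031 alone lower, at -1.97. A dye-dependent position effect is argued against, since the lower of the medians of both orientations was 1.23 ± 0.19. A normalization that differed between replicates is argued against as well, since the lowest replicate's median was 1.04. This is weak, as the block was picked for its median over all arrays. A normalization effect shared by all arrays was not tested. A position effect on the array that follows the sample and not the dye stays open, as no spot positions were used here. Coordinate expression of this region in bacteroids may be the source, which is a hypothesis found and tested on the same data. The block was not the only high stretch at the ends of the numbering. Windows of 30 loci near the other end had medians from 0.70 (loci 8193 to 8222) to 0.81 (loci 8203 to 8232), and these were not tested further.

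fixN, the first gene of fixNOQP, lay at -0.13 beside fixQ and fixP near 3.7. A dye effect is argued against by a mean difference between orientations of -0.22. A probe that measures little of its target remains possible: its SD over 8 arrays, 0.21, stood at percentile 6.63 among the 3999 loci with means within 0.5 of 0. A well measured gene that does not change gives such a value too, so this test favours neither, and a biological difference within the operon was not tested. fixN was not alone in lying near 0. The nearby fixG (blr2767) and fixS (bsr2770) were at 0.03 and 0.02, while fixH (blr2768) and fixI (blr2769) were higher at 1.32 and 0.74.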

How the results depend on the processing

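Among the alternatives, reading the values as natural logs, replicates 1 and 2 or 3 and 4 alone, leaving out loci with a dye difference, and loci with 1 probe were chosen after seeing the data. The alternatives on missing values gave the same result, as no value was missing, and leaving out dim loci was not run, as no signal was at hand. Counts of calls stayed within 1.5 times under both scalings, the replicate block (5514 called) and the block with a dye term (5501 called), and these changed no call of a named gene or list. The replicates' correlation within the block was 0.05, and 0.26 with the dye term. With ordinary t statistics 3719 loci passed, 1641 of them higher, and with a fold of 2 as the bound 929 passed, 373 higher and 556 lower, as fewer loci meet a stricter bound by construction. Natural logs gave 1276 loci at least 2-fold higher and 1736 lower, by construction. Without 1 replicate each, 4620 to 5111 loci passed, 2204 to 2511 higher and 2416 to 2603 lower, with 618 to 788 at least 2-fold higher and 1062 to 1242 lower. The odds ratio of the island block then ranged from 4.73 to 4.88, against 4.155 on forward arrays alone and 11.83 with a fold of 2 as the bound, and 6 to 7 lists were higher and 7 to 8 lower, against 7 and 7 with all replicates. With an estimated correlation 0 lists were higher and 0 lower in camera (2 higher and 1 lower at an unadjusted p under 0.05), and fry, which asks only whether a list's genes move one way, called 13 higher and 12 lower. When genes of more than 1 list were left out, the nitrogen fixation and nodulation lists did not pass, because their members in the island block were then removed. Only fixR (bll2623), nifS (blr4338 and blr4342) and nifR (blr4486) stayed in the first (median -0.49, adjusted p 0.367). The second kept only nodQ (bll1475), nodI (blr0906) and nodN (bll3460 and blr3959), which went both ways (median -0.33, adjusted p 0.65). So few members do not show a change of direction of either list. On forward arrays alone 2 dctA copies not past the threshold otherwise passed, blr6145 as higher (0.37, adjusted p 0.0454) and blr7187 as lower (-0.36, adjusted p 0.0435), and the cause was not tested. With the probe of median size betB was at -0.33, because that is the lower of its probes, the other being at 1.03. No signal over background was at hand, so what array brightness limits is unknown.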

Other observations

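The groups and windows here were chosen after the data were seen, from 19 further groups of gene symbols tested with camera from limma. The cytochrome P450 cluster, outside the island block as fixed, was higher at 4 of 4 members (CYP112, CYP114, CYP117 at 3.60 ± 0.29 and fpps at 3.58 ± 0.38, adjusted p 0.000247, and adjusted p = 0.52 with an estimated correlation). As CYP112 and CYP114 were among the 12 highest named loci, the group's adjusted p is no independent support. The window of 30 loci numbered 2122 to 2151 around the cluster had a median of 2.41, with 27 higher, against a highest window median of 0.91 in 1000 shuffled gene orders. Shuffled orders treat neighbouring genes as independent, so passing this bound says little about the cluster itself. Fatty acid synthesis genes were lower at 17 of 20 members and higher at none (median -0.76, adjusted p 0.000247, and adjusted p = 0.52 with an estimated correlation). Purine and pyrimidine synthesis genes were lower at 15 of 22 and higher at none (median -0.66, adjusted p 0.00471, and adjusted p = 0.543 with an estimated correlation).

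Aminoacyl-tRNA synthetase genes were lower at 14 of 20 members and higher at 3 (alaS at 0.50, pheT at 0.37 and cysS at 0.37, adjusted p of the group 0.0119). Protein export genes were lower at 7 of 11 and higher at 1 (secB at 0.64, adjusted p of the group 0.0204). The ctp pilus genes were lower at 10 of 14 and higher at 2 (ctpD at 0.95 and ctpB at 0.55, adjusted p of the group 0.0423), and none of these 3 groups passed with an estimated correlation (adjusted p = 0.52, 0.543 and 0.52). Molybdenum genes had no common direction (adjusted p 0.832), yet the transporter genes modA (blr6951), modB (blr6952) and modC (blr6953), beside the hydrogenase genes, were at 2.29 ± 0.72, 3.00 ± 0.58 and 1.78 ± 0.77, and modB (blr1719), in the island block, at 3.80 ± 0.40. Cold shock genes named cspA also split, with 4 of 8 higher, up to 2.55 ± 0.11 (bsr3154), and 3 lower. The probes of bsr3154 disagreed, at 1.12 and 3.99. The remaining groups did not pass. The lowest window, loci 5375 to 5404 with the ribosomal protein genes, had a median of -1.58 with 30 of 30 lower.

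Probes assigned to 1 locus by their names often disagreed. What the suffix in some probe names stands for is unknown, and whether both probes measure the same gene was not tested. For 182 loci with a plain and a suffixed probe, the ratios of both correlated across loci with Pearson r 0.49 and Spearman rho 0.31, whereas the plain probes' ratios in replicates 1 and 2 correlated with those in 3 and 4 at r 0.94. The gap between both probes recurred, with r 0.90 between these replicate pairs and 0.88 between dye orientations, and the suffixed probe had the smaller ratio at 91 of 182 loci. Tested separately, both probes passed at 83 loci, and at 27 of these with opposite signs. Most loci had 1 probe, for which no such comparison exists.

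With the signs of the 4 replicates turned in every way, 8 sets are possible, too few for a share under 0.05. The real signs alone (1 of 8) gave 5445 called loci, and the highest other set gave 0.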
